A study of Mus musculus with 18 samples.

How the data were processed

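The data are 18 Affymetrix arrays of mouse retina, 3 for each of 6 groups of treatment (BSS vehicle, DEX or TAA) and day after intravitreal injection (7 or 30). Per the labels' protocols, retinas were taken into RNAlater, total RNA was isolated with a Qiagen RNeasy kit, and biotinylated cRNA was prepared with the two-cycle Affymetrix procedure. Per the labels, the authors processed the arrays with RMA; its version, settings and any filter are not stated. The deposited values are taken as log2 values relative to the median of each probe set over the 18 arrays. RMA's usual scale is log2. The centring was found in the values, since the median over the arrays was within 5e-07 of 0 in 45101 of 45101 probe sets. The values ran from -4.50 to 5.71, and the array medians from -0.0234 to 0.00797. The log base and the direction (higher for more RNA) were taken from RMA's convention and cannot be read from the values, and no array carries a scan date or batch in the labels.

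Because the values are centred, they hold no expression level or signal over background. A filter on level planned before the data were examined (log2 of at least 5 on at least 3 arrays), its stricter alternative (at least 7) and the choice of the probe set of highest mean could not be applied. In their place no genes were filtered, and for a gene with more than 1 probe set (9012 genes) the probe set of highest interquartile range over the 18 arrays, blind to group, was kept. This replacement was chosen after the data were seen. Probe sets were named from the platform's annotation: 34958 named 1 gene, 932 named several and 9160 are unnamed here, and 64 control probe sets were left out. Of the 34958, 34754 had a gene ID found in the RefSeq gene table. Only probe sets of 1 gene were used, which gave 18193 genes.

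Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 18 arrays (12 residual degrees of freedom, 5.21 prior degrees of freedom) and no further normalization. Empirical Bayes moderation used its default settings, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The comparisons were each drug against vehicle at each day, DEX against TAA at each day, vehicle between the days, the change of each drug effect between the days, and 5 pooled drug effects. The comparisons, the tests, the 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named genes that passed and whose groups did not overlap (up to 10 per direction). Where under 5 passed, it also named the 5 highest and 5 lowest differences among the 100 genes of smallest p. It named the 4 members of smallest p of each list that passed, 10 genes in every drug comparison (Fkbp5, Tsc22d3, Per1, Sgk1, Zbtb16, Gfap, Nr3c1, Vegfa, Aqp4 and Kcnj10) and up to 3 members of lists for adjacent tissue. Predicted genes, RIKEN and numbered clone symbols were counted and not named. Further members of a list that passed when adjusted over the list alone are also named, and these were chosen after their values were seen. A result that the rule would name is not reported here.

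Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists within a comparison, and again with the correlation estimated from the data. The lists covered the glucocorticoid response, reactive gliosis, Müller glia, rods, cones, bipolar cells, amacrine and horizontal cells, ganglion cells, pigment epithelium, crystallins, other lens fibre genes, the anterior segment, vascular endothelium, pericytes and smooth muscle, angiogenesis, microglia and leukocytes, complement, inflammatory mediators, interferon and antigen presentation, immediate early and heat shock genes, cell death, extracellular matrix, water and ion transport, the circadian clock, erythrocytes, the cell cycle, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins and synapses. They name 576 distinct genes, of which 520 were measured and 56 were not, and 4 were matched by an older symbol. For each list the mean log2 difference over members is given with a 95% interval from the spread of the list's mean between arrays. This spread was pooled over the 6 groups and assumed equal in all of them. The interval is therefore too narrow where the compared groups spread more widely than the rest.

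The fit was tested on simulated data for TAA against BSS at day 7, with 18193 genes, independent normal noise of each gene's residual SD, and 200 changed genes in each of 5 draws. Of the changed genes, 32.8% of those changed by a log2 of 0.5 were called in the right direction, 87.8% of those changed by 1 and 99.4% of those changed by 2, with 0.04% of unchanged genes called. In 100 draws with no effect, built by shuffling the real residuals between arrays, camera with the preset correlation called a mean of 5.56 of 30 lists and at least 1 list in 94 draws. Camera with an estimated correlation called a mean of 0.07 lists and at least 1 in 5 draws. A list that passes with the preset correlation alone is therefore weak evidence. The shuffling moved arrays of wide spread, such as TAA day 7 replicate 2, between the groups. The low rate with the estimated correlation may therefore not hold for comparisons that include such an array.

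Titles give the replicates of every group the numbers 1 to 3, and the labels do not say that a number links animals. Each animal code in the descriptions occurs once, so no animal code links arrays. The limit for deviations of arrays with the same number was a correlation over 0.1 in every pair, set beforehand. Only DEX and BSS at day 30 met it (0.111, 0.123 and 0.282). Deviations of arrays with different numbers were not compared, so this check cannot show that the numbers pair the arrays in any comparison. The reported fit has no block in any comparison, as planned. A fit with the replicate number as a block was run for every comparison, and for DEX against BSS at day 30 it still called 0 genes and 4 lists. The other alternatives were every probe set tested, the mean of a gene's probe sets, quantile normalization, a common array median, only the compared arrays, a variance trend with robust moderation, array quality weights, an adjusted p under 0.1, a 1.5-fold minimum and each array left out in turn. The array quality weights were estimated from these same values, so an array unlike its group counted less. The count of single-gene differences that rest on 1 array was chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.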

Results

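The study measured gene expression in the retina of 2-month-old male C57BL6/J mice after a single intravitreal injection. Eyes received dexamethasone (DEX), triamcinolone (TAA in the labels) or the vehicle (BSS), and retinas were taken at day 7 or day 30. Each of the 6 groups of treatment and day held 3 biological replicates, each on its own Affymetrix array, which gave 18 arrays. The deposited values are relative log2 values, centred on 0 for every probe set, so they give differences between arrays and no expression level. After 1 probe set was kept per gene, 18193 genes were compared. The residual standard deviation within groups had a median of 0.18 log2 units over genes, and the number of arrays limits the precision of every difference below. Differences are given on the log2 scale with their standard error, and every group has n = 3. Many values of single genes rest on 1 array. Of the 466 differences of single genes examined, 142 shrank to under 0.5 of their value in some fit that left out 1 array, and 42 of these turned their sign.

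In the centred values, the arrays of 1 group resembled each other only slightly. Centring takes out what all arrays share, so these correlations say nothing of likeness in expression level. It also pushes the correlation of unrelated arrays slightly below 0. Across genes, the correlation between 2 arrays had a median of 0.118 for the 18 pairs within a group and -0.0713 for the 135 pairs between groups. Genes are not independent replicates, so these values describe the arrays and carry no test. BSS day 7 replicate 1 had the lowest mean correlation with its group mates (-0.190, with -0.171 and -0.208 for the single pairs), against 0.336 with DEX day 7 replicate 1, and it is a control in each comparison of a drug with vehicle at day 7. The widest spread over all probe sets was found on TAA day 30 replicate 2 (SD 0.350) and TAA day 7 replicate 2 (SD 0.338), against 0.147 on TAA day 7 replicate 3. On TAA day 30 replicate 2 the 3' minus 5' value of the Actb control probe sets was -0.459 relative to the median array. The other 17 arrays lay between -0.167 and 0.137. The same value for the Gapdh control probe sets was -0.086 on that array, and it was highest on DEX day 7 replicate 2 (0.284). Whether these values reflect RNA quality was not tested. The ribosomal protein genes averaged -0.63 on TAA day 30 replicate 2. On those 2 wide arrays the 23 rod photoreceptor genes tested averaged -0.17 and -0.21, and on TAA day 30 replicate 3 the 14 crystallin genes, which encode the structural proteins of the lens, averaged 3.44. The members differed there, with Cryaa at 5.70 and Crygs at 5.49 but Crygb at -0.279 and Crygd at -0.045.

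Triamcinolone at day 7 was compared with vehicle at day 7 to ask what the drug changed early. Folh1, which encodes glutamate carboxypeptidase II, an enzyme that releases glutamate from N-acetylaspartylglutamate, rose by 1.87 ± 0.26 (3.65-fold), and its 3 TAA arrays all lay above the 3 vehicle arrays. As a group, the glucocorticoid response genes were higher by a mean of 0.53 (95% interval 0.27 to 0.78) and a median of 0.29, with 25 of the 31 measured members above vehicle. The list's mean had an SD of 0.31 on the TAA arrays and 0.03 on the vehicle arrays. The interval, from a spread pooled over all groups, understates the spread of the TAA arrays. Of these 31 genes, 9 rose when adjusted over the list alone, against 0 adjusted over all genes tested. They were Zbtb16, a zinc finger transcription factor (0.83 ± 0.16), Arrdc2, an arrestin-domain gene (1.02 ± 0.21), Fam107a, a stress-inducible actin-binding gene (1.15 ± 0.24), the metallothioneins Mt1 (1.10 ± 0.28) and Mt2 (1.54 ± 0.38), and the sulfotransferase Sult1a1 (0.87 ± 0.21). The others were the repressor Bcl6 (0.62 ± 0.20), Fkbp5, a co-chaperone of the glucocorticoid receptor (0.88 ± 0.29), and Glul, the glutamine synthetase of Müller glia (0.33 ± 0.11). Fkbp5 rested mostly on TAA day 7 replicate 1 and was at 0.35 without it. Other familiar members did not pass: Tsc22d3 was at 0.13 ± 0.14, Per1 at -0.09 ± 0.13, Sgk1 at -0.04 ± 0.11 and the receptor gene Nr3c1 at -0.22 ± 0.14.

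Reactive gliosis genes were also higher at day 7 after TAA, by a mean of 0.98 (95% interval 0.14 to 1.82), in 18 of 21 members. The pooled interval again understates the spread of the TAA arrays, with an SD of 0.84 against 0.20 in vehicle. The call of this list was lost when the correlation between its genes was estimated (adjusted p = 0.179 with an estimated correlation, against 3.54e-13 with the preset one). Adjusted over the list alone, 6 members rose, against 0 over all genes: the protease inhibitors Serpina3n (2.98 ± 0.78) and A2m (1.94 ± 0.53), the glial filament gene Gfap (1.20 ± 0.40), the copper-binding ferroxidase gene Cp (1.26 ± 0.43), the metalloproteinase inhibitor Timp1 (1.40 ± 0.48) and the growth arrest gene Gadd45b (1.25 ± 0.45). The 3 TAA arrays differed widely in this list, with means of 0.60, 1.64 and -0.03, and the list mean dropped to 0.53 without TAA day 7 replicate 2. Without that array A2m was at 1.07, Gfap at 0.63, Cp at 0.62 and Timp1 at 0.60. Bipolar cell genes averaged 0.17 higher, with Vsx1 at 0.46 ± 0.14, Scgn at 0.35 ± 0.14, Lrtm1 at 0.40 ± 0.19 and Cabp5 at 0.28 ± 0.15 (list adjusted p = 0.0552 with an estimated correlation). Extracellular matrix genes averaged 0.19 higher, with Mgp at 0.64 ± 0.22, Sparc at 0.47 ± 0.17 and Postn at 0.45 ± 0.17 (list adjusted p = 0.331 with an estimated correlation). Without TAA day 7 replicate 2 the means of the bipolar and matrix lists were 0.10 and 0.07 and neither passed, and Lrtm1 was at 0.14.

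Among genes of the tissue next to the retina, Kcnj13, the inward rectifier potassium channel of the retinal pigment epithelium, fell by 0.997 ± 0.217 when adjusted over its list alone (adjusted p = 0.00458). It did not pass over all genes (adjusted p = 0.494). Rrh of the same list went the other way (-0.08, 0.50 and 0.51 after TAA, -0.18, -0.11 and 0.06 in vehicle). Stra6 was lower (0.05, -0.20 and -0.40 against 0.07, 0.08 and 0.12). All samples are retina, and how much pigment epithelium each carried was not tested. The 18 pigment epithelium genes as a group did not pass (mean -0.26, adjusted p = 0.0521 with the preset correlation). Genes with large differences that did not pass over all genes included the acute phase gene Saa3 (2.02 ± 0.39), Selenbp1 (2.51 ± 0.59), and on the lower side the phospholipid transfer gene Pltp (-0.55 ± 0.17), the transcription factor gene Foxp2 (-0.57 ± 0.16), Plekhg4 (-0.67 ± 0.19) and the chromatin remodelling gene Baz1a (-0.55 ± 0.15). Without TAA day 7 replicate 1, Selenbp1 was at 1.33. Vegfa, the target of many retinal therapies, was at -0.17 ± 0.15, the water channel Aqp4 at 0.40 ± 0.27 and the potassium channel Kcnj10 at 0.08 ± 0.18. Aqp4 was at -0.05 without TAA day 7 replicate 2.

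By limma, 1 of the 18193 genes passed in this comparison (Folh1, adjusted p = 0.0236), and 719 genes had an unadjusted p under 0.05, where chance gives 909.7. The groups' arrays did not overlap for 9.32% of genes, where chance gives 10%. The Folh1 call was lost in 5 of the 6 fits that left out 1 array, with differences of 1.58 to 2.15, and in 3 other fits. Without TAA day 7 replicate 3 the test called 15 genes, and with arrays weighted by their quality it called 49. Here and below, these weights reflect how closely an array follows its own group, and they are no independent measure of quality. The glucocorticoid list had an adjusted p of 1.01e-14 with the preset correlation and 0.00844 with an estimated one, and it passed with the estimated correlation in 6 of 6 fits that left out 1 array (adjusted p 2.75e-05 to 0.0482). Its means on the 3 TAA arrays were 0.66, 0.65 and 0.12, each above all 6 other day 7 arrays, which pool vehicle and DEX. An exact permutation test of this split gave a two-sided p = 0.0119, the smallest that the 84 splits allow. Against the 3 vehicle arrays alone, an exact permutation test gave a two-sided p = 0.1, the smallest possible there. The same tests were run for the gliosis, microglia, interferon and crystallin lists and for each drug and day, without adjustment for their number. Among the other permutation tests against the 6 other arrays, the smallest p was 0.143, for gliosis after TAA at day 7 and glucocorticoid genes after TAA at day 30. The value of 0.0119 could not stay under 0.05 if adjusted over all these tests.

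**Figure D1:**
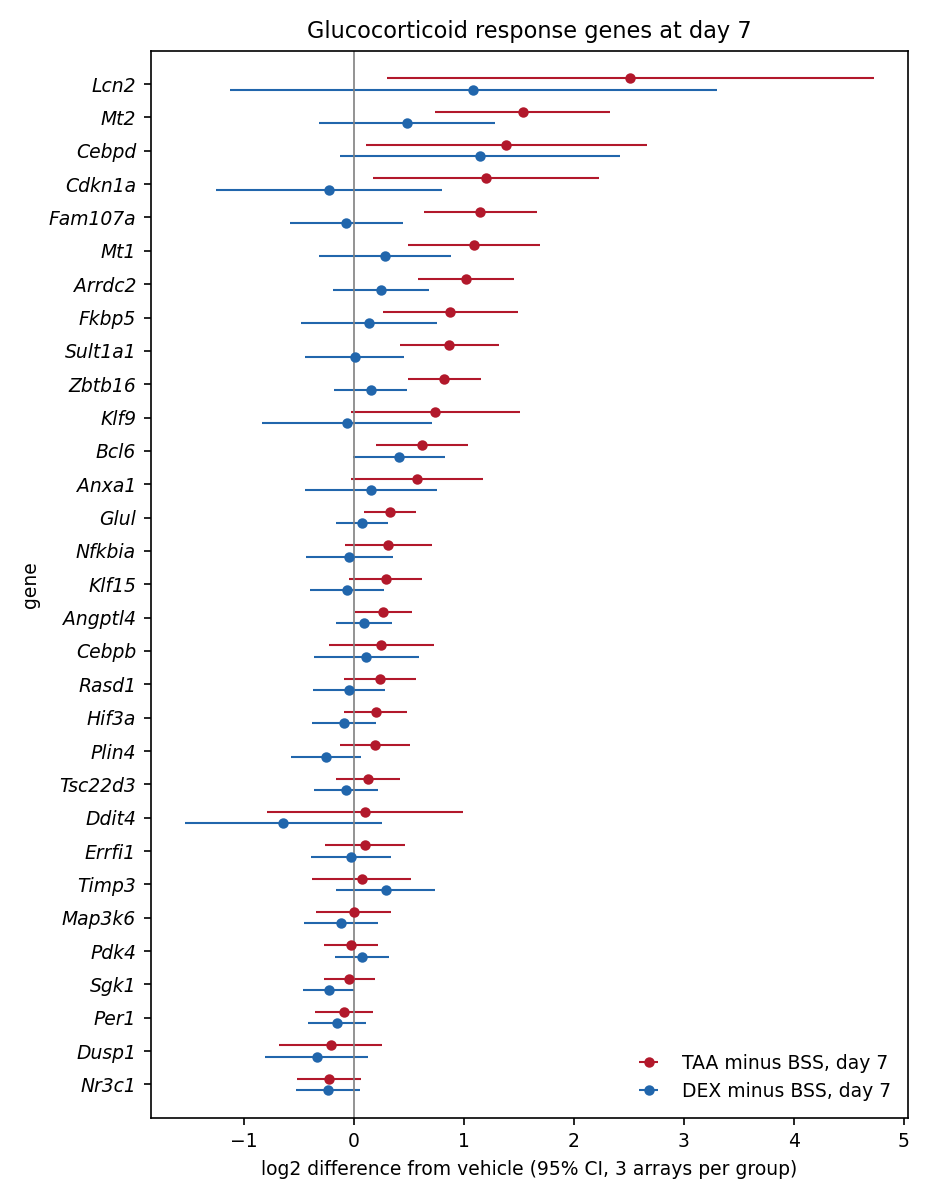
Log2 difference from vehicle at day 7 (horizontal axis) for each of the 31 measured glucocorticoid response genes, with TAA in red and DEX in blue; points are limma estimates from 3 arrays per group and lines are 95% intervals. The TAA estimates lie above 0 for 25 of 31 genes with a mean of 0.53, and the DEX estimates have a mean of 0.07.

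Dexamethasone at day 7 was compared with the same vehicle arrays. The glucocorticoid response genes averaged 0.07 (95% interval -0.19 to 0.33; adjusted p = 0.938 with the preset correlation), with Fkbp5 at 0.14 ± 0.29, Zbtb16 at 0.15 ± 0.16, Tsc22d3 at -0.07 ± 0.14, Per1 at -0.15 ± 0.13 and Sgk1 at -0.23 ± 0.11. Reactive gliosis genes averaged 0.72 higher (95% interval -0.12 to 1.56), with higher values in 19 of 21 members, among them Serpina3n (1.77 ± 0.78), Cp (1.13 ± 0.43), the growth factor Fgf2 (0.68 ± 0.25), the signalling gene Stat3 (0.49 ± 0.21) and Gfap (0.75 ± 0.40). The list passed with the preset correlation and its call was lost otherwise (adjusted p = 0.195 with an estimated correlation). Fgf2 was at 0.32 without DEX day 7 replicate 1. The list means on the 3 DEX arrays were 0.55, 0.52 and 0.37, against -0.09, -0.47 and -0.16 in vehicle.

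In total, 12 of the 30 lists passed with the preset correlation in the DEX comparison at day 7, and 0 with an estimated one. Interferon and antigen presentation genes averaged 0.46 higher, with the antiviral genes Ifit1 (1.02 ± 0.53) and Rsad2 (0.77 ± 0.44), the GTPase Gbp2 (0.96 ± 0.48) and Stat2 (0.28 ± 0.15); adjusted p = 0.417 with an estimated correlation. Rsad2 was at 0.23 without DEX day 7 replicate 3. Microglia and leukocyte genes averaged 0.36 higher, with the receptors P2ry12 (0.48 ± 0.21), Cx3cr1 (0.53 ± 0.29), Fcgr3 (0.49 ± 0.30) and Csf1r (0.50 ± 0.30); adjusted p = 0.455 with an estimated correlation. Extracellular matrix genes averaged 0.23 higher, with the collagens Col3a1 (1.42 ± 0.44) and Col1a2 (0.68 ± 0.25), Sparc (0.42 ± 0.17) and fibronectin, Fn1 (0.36 ± 0.15); adjusted p = 0.195 with an estimated correlation. Of the neuronal lists, 3 passed, with bipolar cell genes higher by 0.17 (Cabp5 0.44 ± 0.15, Vsx1 0.39 ± 0.14, Prkca 0.64 ± 0.26). Amacrine and horizontal cell genes were higher by 0.18 (Dab1 0.63 ± 0.24, Gad2 0.47 ± 0.25, Prox1 0.73 ± 0.39) and synapse genes by 0.18 (Bsn 0.40 ± 0.14, Gria1 0.39 ± 0.15, Syt1 0.68 ± 0.29). Their adjusted p = 0.0901, 0.0901 and 0.135 with an estimated correlation, in that order. The ganglion cell (-0.02), rod (-0.02) and cone (-0.08) lists did not pass. Angiogenesis and permeability genes averaged 0.14 higher (Kdr 0.52 ± 0.18, Hif1a 0.79 ± 0.34, Icam1 0.26 ± 0.15; adjusted p = 0.0901 with an estimated correlation), while Vegfa was at -0.08 ± 0.15. Müller glia markers averaged 0.15 higher (Dkk3 0.55 ± 0.20, Slc1a3 0.63 ± 0.26, Crym 0.65 ± 0.34, Cd9 0.39 ± 0.20; adjusted p = 0.417 with an estimated correlation), with Aqp4 at 0.05 ± 0.27 and Kcnj10 at 0.14 ± 0.18. Without BSS day 7 replicate 1, Hif1a was at 1.29 and Prox1 at 1.11.

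Of the 12 lists that passed after DEX at day 7, 3 were below vehicle. Pigment epithelium genes averaged -0.37, with the melanosome genes Pmel (-0.64 ± 0.37) and Dct (-1.03 ± 0.60), the retinol dehydrogenase Rdh5 (-0.53 ± 0.28) and Kcnj13 (-0.37 ± 0.22); adjusted p = 0.142 with an estimated correlation. Without BSS day 7 replicate 1, Pmel was at -0.07 and Dct at -0.29, and without DEX day 7 replicate 2 the list mean was -0.24. Crystallins averaged -0.77, with Cryba1 at -2.17 ± 1.51 and Crygs at -1.97 ± 1.45 (adjusted p = 0.53 with an estimated correlation), and their call was also lost in 4 of the 6 fits that left out 1 array. Ribosomal protein genes averaged -0.13, with Rps19 at -0.18 ± 0.10 and Rpl35 at -0.27 ± 0.19 (adjusted p = 0.524 with an estimated correlation), and did not pass without DEX day 7 replicate 3 (-0.11). No member of these 12 lists passed when adjusted over the list alone or over all genes. By limma, 0 genes passed (smallest adjusted p = 0.79), and 711 had an unadjusted p under 0.05, where chance gives 909.7; a fit on the 6 compared arrays alone called 2. The arrays did not overlap for 14.3% of genes, where chance gives 10%. Among them were the amino acid transporter Slc43a2 (1.19 ± 0.23), the nuclear envelope gene Syne2 (1.15 ± 0.34), Ypel2 (1.11 ± 0.33) and the mitochondrial carrier Slc25a5 (-0.51 ± 0.14). Syne2 was at 1.61 and Ypel2 at 1.54 without BSS day 7 replicate 1. Weighting arrays by their quality called 164 genes.

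Dexamethasone and triamcinolone are both fluorinated derivatives of prednisolone, and dexamethasone carries a methyl group on the D ring at the carbon where triamcinolone carries an oxygen substituent. The labels give no dose, so the drugs were compared at matched days without matched doses. At day 7 the glucocorticoid response genes were lower after DEX than after TAA by a mean of -0.46 (95% interval -0.71 to -0.20), in 29 of 31 members. The list passed both with the preset correlation (adjusted p = 1.28e-12) and with an estimated one (adjusted p = 0.016). Adjusted over the list alone, 8 members fell, against 0 over all genes: Fam107a (-1.22 ± 0.24), Zbtb16 (-0.67 ± 0.16), Sult1a1 (-0.86 ± 0.21), Arrdc2 (-0.77 ± 0.21), the lipid droplet gene Plin4 (-0.45 ± 0.15), the cell cycle inhibitor Cdkn1a (-1.43 ± 0.49), Mt1 (-0.81 ± 0.28) and Mt2 (-1.05 ± 0.38). Folh1 fell by 1.77 ± 0.26 in the DEX arrays relative to the TAA arrays.

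Microglia and leukocyte genes were higher after DEX than after TAA at day 7 in 21 of 21 members, by a mean of 0.48 (95% interval -0.28 to 1.25; adjusted p = 0.841 with an estimated correlation). The fractalkine receptor Cx3cr1 (1.24 ± 0.29), the purinergic receptor P2ry12 (0.85 ± 0.21) and the growth factor receptor Csf1r (1.08 ± 0.30) rose when adjusted over the list alone, against 0 over all genes, and Tmem119 was at 0.35 ± 0.13. The list mean was 0.83 without TAA day 7 replicate 2 and 0.24 without TAA day 7 replicate 1. Immediate early and heat shock genes averaged -0.21, with Egr1 at -0.80 ± 0.28 and Nr4a1 at -0.32 ± 0.17 (adjusted p = 0.59 with an estimated correlation). The list did not pass without TAA day 7 replicate 2 (-0.12) or DEX day 7 replicate 3 (-0.17). Ribosomal protein genes averaged -0.17, with Rps6 at -0.38 ± 0.13 and Rpl4 at -0.33 ± 0.17 (adjusted p = 0.924 with an estimated correlation), and did not pass without TAA day 7 replicate 3 (-0.11) or DEX day 7 replicate 3 (-0.14). No difference between the drugs passed for reactive gliosis (-0.26, 95% interval -1.10 to 0.58), Gfap (-0.45, -1.30 to 0.39), Vegfa (0.08, -0.23 to 0.39), Aqp4 (-0.35, -0.92 to 0.22), Tsc22d3 (-0.20, -0.49 to 0.09) or Kcnj13 (0.63, 0.17 to 1.09; adjusted p = 0.178 over its list alone). Without TAA day 7 replicate 2, Gfap turned to 0.12 and Aqp4 to 0.10. The order of the drugs then turned for the gliosis list too, at 0.53 over vehicle after TAA against 0.72 after DEX. By limma, 1 gene passed (Folh1, adjusted p = 0.0472), and 1177 had an unadjusted p under 0.05, where chance gives 909.7; the arrays did not overlap for 11.7% of genes, where chance gives 10%. The Folh1 call was lost in 5 of the 6 fits that left out 1 array and in 5 other fits. Without TAA day 7 replicate 3 the test called 5 genes, and with arrays weighted by their quality it called 747.

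**Figure D2:**
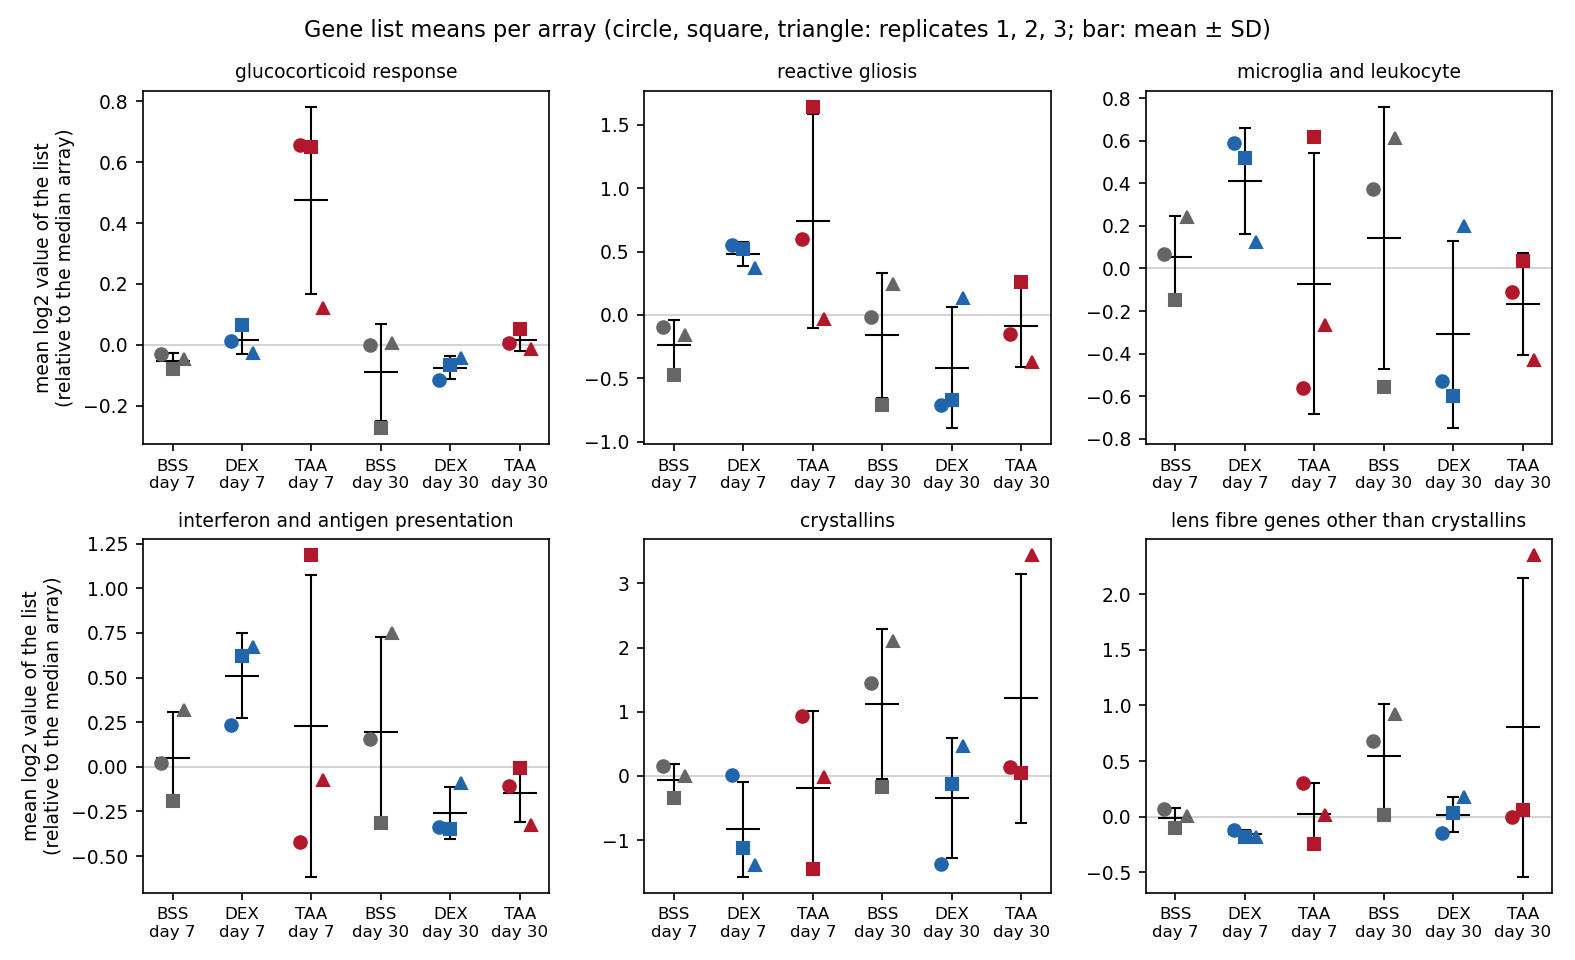
Mean log2 value (vertical axis, relative to each probe set's median over all arrays) of 6 gene lists on each of the 18 arrays, by treatment and day (horizontal axis); points are arrays, and bars show the mean and SD of 3 arrays. The glucocorticoid list lies at 0.66, 0.65 and 0.12 on the TAA day 7 arrays, the gliosis list spans -0.03 to 1.64 on the same arrays, and the crystallin list reaches 3.44 on TAA day 30 replicate 3.

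Dexamethasone at day 30 was compared with vehicle at day 30 to ask what remained or appeared late. Gfap was lower by -1.36 ± 0.40, with all 3 DEX arrays below the vehicle arrays, but did not pass over all genes (adjusted p = 0.362). The reactive gliosis list as a whole averaged -0.25 and did not pass. Microglia and leukocyte genes averaged -0.45 (95% interval -1.22 to 0.31) with lower values in 20 of 21 members. Among them Tmem119, a membrane protein of resident microglia, fell by 0.53 ± 0.13 when adjusted over the list alone, against 0 over all genes. The other leading members were the antigen presentation gene Cd74 (-0.76 ± 0.25), Cd52 (-0.64 ± 0.25) and Csf1r (-0.63 ± 0.30). Interferon and antigen presentation genes averaged -0.45 (Ifi27 -0.66 ± 0.32, Psmb8 -0.51 ± 0.27, Irf7 -0.29 ± 0.16, Ifit1 -0.97 ± 0.53). Complement genes averaged -0.36 (Cfb -0.36 ± 0.15, Cd46 -0.38 ± 0.16, Clu -0.37 ± 0.21, C1qc -0.93 ± 0.53), and crystallins averaged -1.47 (Crygb -1.54 ± 0.78, Crygd -1.61 ± 0.82, Crybb2 -2.07 ± 1.12, Crybb1 -1.73 ± 0.96). These 4 lists passed with the preset correlation and none did otherwise (adjusted p = 0.848 for each with an estimated correlation). Without BSS day 30 replicate 3, none of the 30 lists passed, and the microglia mean was -0.22, the interferon mean -0.18, the complement mean -0.21 and the crystallin mean -0.98. Cd74 was then at -0.32, Ifi27 at -0.24, Crygb at -0.61 and Crygd at -0.71. Leaving out BSS day 30 replicate 2 moved the means the other way, to -0.80 for microglia, -0.71 for interferon, -0.57 for complement and -2.12 for crystallins.

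The glucocorticoid response genes averaged 0.01 at day 30 after DEX (95% interval -0.24 to 0.27), with Fkbp5 at -0.16 ± 0.29, Zbtb16 at 0.11 ± 0.16, Tsc22d3 at 0.05 ± 0.14 and Per1 at -0.23 ± 0.13. Aqp4 was at 0.59 ± 0.27, Kcnj10 at 0.21 ± 0.18, Nr3c1 at 0.26 ± 0.14 and Vegfa at -0.11 ± 0.15. The lysosomal protease Lgmn (-1.08 ± 0.25), the prohormone convertase inhibitor Pcsk1n (-0.81 ± 0.17), Cd99 (-0.79 ± 0.19), C1qtnf4 (-0.87 ± 0.21), Sbf1 (-0.82 ± 0.19) and the ectoenzyme Bst1 (1.81 ± 0.48) were among the genes with the largest differences, and none passed. By limma, 0 genes passed (smallest adjusted p = 0.354), and 2100 had an unadjusted p under 0.05, where chance gives 909.7. The arrays did not overlap for 14.4% of genes, where chance gives 10%. DEX day 30 replicate 3 was unlike the others of its group: replicates 1 and 2 correlated at 0.690 with each other across genes and at -0.0597 and -0.101 with replicate 3. The spread over all probe sets was wider on replicates 1 and 2 (SD 0.265 and 0.297) than on replicate 3 (SD 0.212). Which of these arrays departs from a usual response cannot be told from these values. Microglia genes averaged -0.53 and -0.60 on replicates 1 and 2 and 0.20 on replicate 3, and gliosis genes averaged -0.71, -0.67 and 0.14. Without replicate 3 the same test called 695 genes, without BSS day 30 replicate 2 it called 3, and with arrays weighted by their quality it called 2699. The weights come from these same values and were 0.273 for replicate 3, against 1.86 and 0.79 for replicates 1 and 2. The weighted count is therefore not independent of leaving replicate 3 out.

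Triamcinolone at day 30 was compared with the same vehicle arrays. Microglia and leukocyte genes averaged -0.31 (95% interval -1.08 to 0.45), with lower values in 19 of 21 members (Tmem119 -0.29 ± 0.13, Cd74 -0.53 ± 0.25, Aif1 -0.38 ± 0.21, Ly86 -0.69 ± 0.40). Interferon and antigen presentation genes averaged -0.34 with lower values in 21 of 22 members, among them the transcription factor Irf7 (-0.50 ± 0.16), Ifit1 (-1.13 ± 0.53) and Mx1 (-0.21 ± 0.12). No member of either list passed, and both calls were lost otherwise (adjusted p = 0.987 for each with an estimated correlation); without BSS day 30 replicate 3 the means were -0.08 and -0.07 and Cd74 was at -0.10. Without BSS day 30 replicate 2 the microglia mean was -0.66 and the interferon mean -0.60. Without TAA day 30 replicate 2, the array of widest spread, both means were -0.41, 4 lists passed with the preset correlation and 0 genes passed. The glucocorticoid response genes averaged 0.10 (95% interval -0.15 to 0.36), with Tsc22d3, a leucine zipper gene that glucocorticoids induce, at 0.38 ± 0.14 (adjusted p = 0.619), Fkbp5 at 0.08 ± 0.29, Zbtb16 at 0.17 ± 0.16, Per1 at -0.10 ± 0.13 and Sgk1 at 0.04 ± 0.11. Gfap was at -0.67 ± 0.40, Vegfa at 0.16 ± 0.15, Aqp4 at -0.11 ± 0.27 and Kcnj10 at -0.05 ± 0.18. The reactive gliosis list averaged 0.07 and did not pass.

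Among the largest differences at day 30 after TAA that did not pass were the tight junction gene Cldn2 (1.15 ± 0.34), the opioid precursor Penk (1.13 ± 0.30), the basement membrane collagen Col4a1 (0.83 ± 0.23), and the zinc transporter Slc39a2 (0.80 ± 0.16). On the lower side were the immediate early genes Egr1 (-1.04 ± 0.28) and Fos (-0.80 ± 0.22), the ubiquitin ligase Nedd4 (-0.92 ± 0.21) and Zfp800 (-1.81 ± 0.42). By limma, 0 genes passed (smallest adjusted p = 0.0551), and 1318 had an unadjusted p under 0.05, where chance gives 909.7. Array quality weights, the replicate number as a block and the mean of a gene's probe sets each called 1. The arrays did not overlap for 13.4% of genes, where chance gives 10%. Crystallins differed from vehicle by 0.08 as a group, with means of 0.14, 0.05 and 3.44 on the 3 TAA arrays, and the corneal enzyme gene Aldh3a1 was at 1.33 ± 0.69. Without TAA day 30 replicate 3, Aldh3a1 was at -0.08 and Col4a1 at 0.48.

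Between the drugs at day 30, crystallins were lower after DEX by a mean of -1.55 (95% interval -3.61 to 0.51), with Cryaa at -3.06 ± 1.39, Crybb1 at -2.32 ± 0.96, Cryba4 at -2.27 ± 1.01 and Crygn at -0.93 ± 0.40. The call was lost otherwise (adjusted p = 0.91 with an estimated correlation), and without TAA day 30 replicate 3 or DEX day 30 replicate 1 the list means were -0.44 and -1.04 and did not pass. With quantile normalization the crystallin mean was -0.66 and did not pass either (adjusted p = 0.185 with the preset correlation). Lens fibre genes other than crystallins had a mean of -0.78 in the same comparison and did not pass (Bfsp2 -0.88 ± 0.42, Lim2 -0.82 ± 0.40, Gja3 -1.603 ± 0.774). Without TAA day 30 replicate 3 these 3 genes were at -0.21, -0.09 and -0.03, and Cryaa was at -1.30, Crybb1 at -0.79, Cryba4 at -0.60 and Crygn at -0.13. The glucocorticoid response genes differed by -0.09, with an interval of -0.35 to 0.17. The values for single genes, none of which passed, were -0.24 for Fkbp5 (-0.85 to 0.38), -0.05 for Zbtb16 (-0.39 to 0.28), -0.34 for Tsc22d3 (-0.63 to -0.05), 0.70 for Aqp4 (0.13 to 1.27), -0.69 for Gfap (-1.54 to 0.15) and -0.27 for Vegfa (-0.58 to 0.04). Without TAA day 30 replicate 2, Gfap was at -0.33 and Vegfa at -0.09. The folate receptor Folr1 (-0.92 ± 0.18) and the noncoding transcript Vax2os (-0.93 ± 0.18) came nearest to passing (adjusted p = 0.0633 for each). They were followed by the gamma tubulin Tubg2 (-1.02 ± 0.21), Col4a1 (-1.07 ± 0.23) and the adaptor protein gene Ywhaz (1.88 ± 0.39). Col4a1 was at -0.72 without TAA day 30 replicate 3. By limma, 0 genes passed, and 3020 had an unadjusted p under 0.05, where chance gives 909.7; the arrays did not overlap for 14.8% of genes, where chance gives 10%. The test called 1253 genes without DEX day 30 replicate 3 and 3 without TAA day 30 replicate 1. It called 2367 with arrays weighted by their quality, 101 with the replicate number as a block and 323 at an adjusted p under 0.1.

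Vehicle-injected eyes were compared between the days. Relative to day 7, 5 genes fell by day 30, among them Jchain, the joining chain of secreted immunoglobulins (by 1.32 ± 0.16), the collagen Col19a1 (by 1.26 ± 0.18), the transcription factor Foxp2 (by 0.98 ± 0.16) and a RIKEN clone gene. For Jchain, Col19a1 and Foxp2, all 3 day 30 arrays lay below all 3 day 7 arrays. Only 4 of the 6 Foxp2 probe sets had the same sign, and with the mean of its probe sets Foxp2 was at -0.18 and did not pass. Retinal ganglion cell genes averaged -0.19 with lower values in 15 of 16 members, among them the transcription factors Pou4f1 (-0.68 ± 0.28), Ebf1 (-0.44 ± 0.17) and Eomes (-0.34 ± 0.15), and Sncg (-0.24 ± 0.12). Crystallins averaged 1.19 (Crybb2 1.92 ± 1.12, Crygd 1.27 ± 0.82, Crygb 1.09 ± 0.78, Crybb3 1.36 ± 0.996). Lens fibre genes averaged 0.55 (Mip 1.45 ± 0.92, Bfsp2 0.72 ± 0.42, Lim2 0.60 ± 0.40), and both lists were higher in every measured member. These 3 lists passed with the preset correlation only (adjusted p = 0.976 for each with an estimated correlation), and without BSS day 30 replicate 3 none passed (crystallins 0.70, lens fibre genes 0.36, ganglion cell genes -0.16). Crygd was then at 0.36, Crygb at 0.16 and Crybb3 at 0.61.

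By limma, the 5 genes of the vehicle comparison had adjusted p-values from 0.00419 (Jchain) to 0.0325 (Foxp2), and 1420 genes had an unadjusted p under 0.05, where chance gives 909.7. The arrays did not overlap for 22.8% of genes, where chance gives 10%. The count was 5 without BSS day 7 replicate 1, 2 without BSS day 30 replicate 3 and 0 without any 1 of the other 4 arrays; quantile normalization called 50, of which 9 were higher and the others lower, against 0 higher and 5 lower. Array quality weights called 527, also in both directions.

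**Figure D3:**
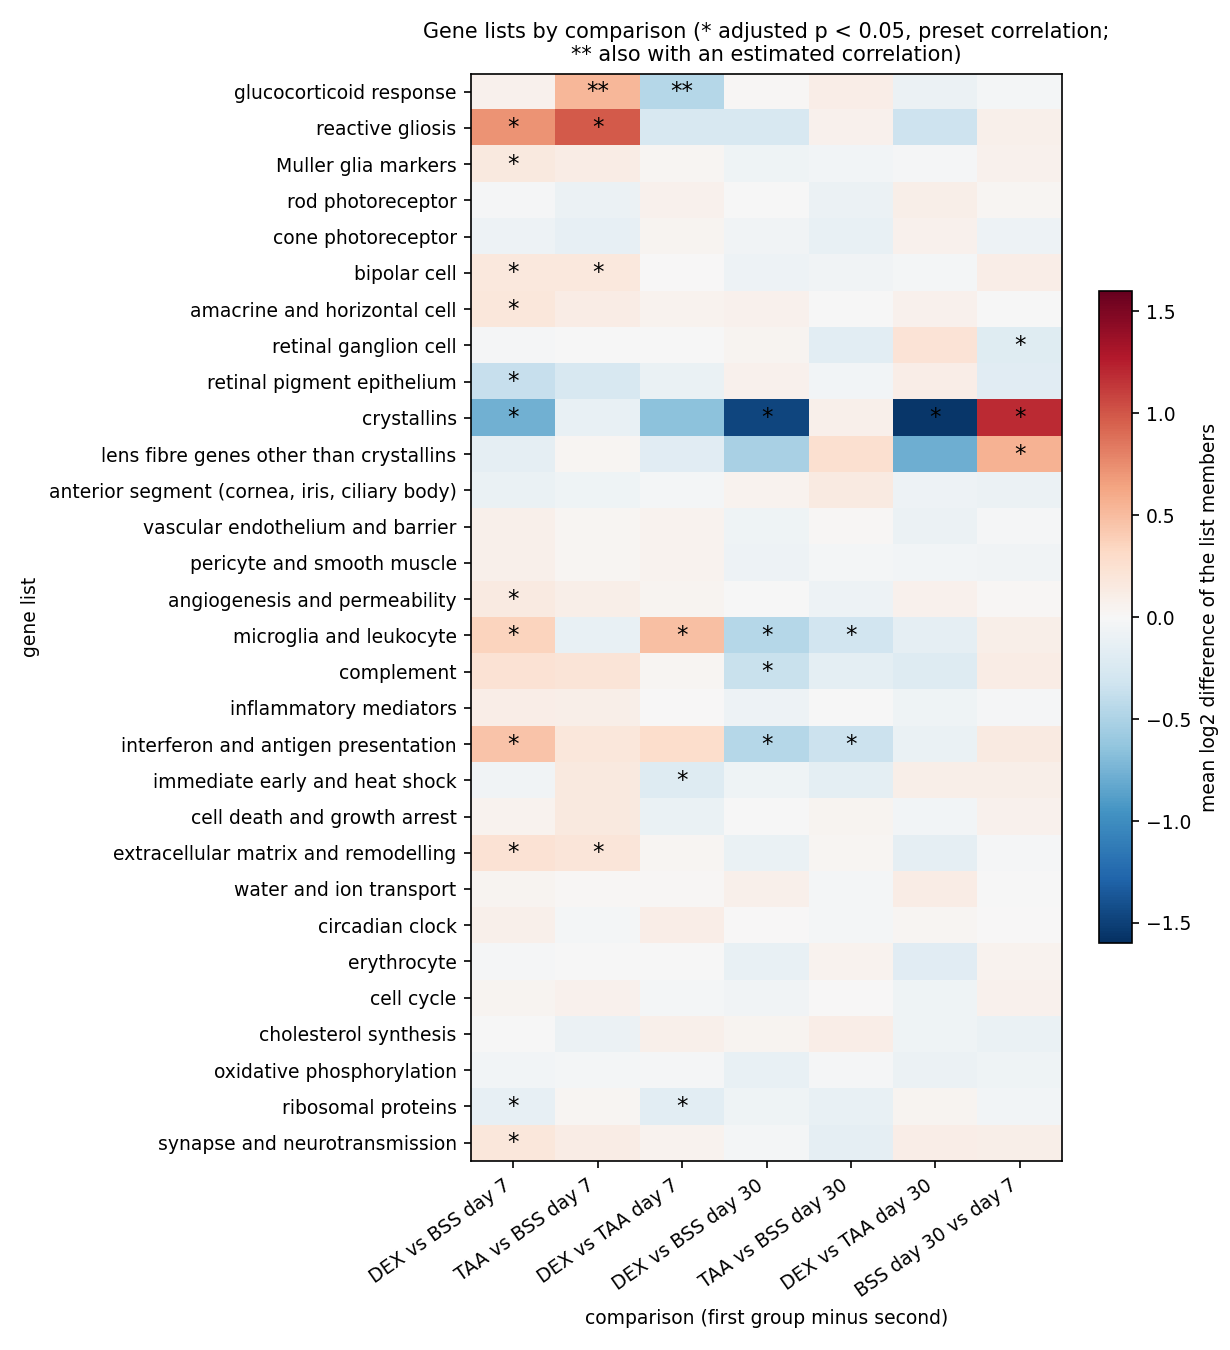
Mean log2 difference (colour scale) of the 30 gene lists (vertical axis) in 7 comparisons of 3 arrays against 3 (horizontal axis); a single star marks an adjusted p under 0.05 with the preset correlation and a double star one that also holds with an estimated correlation. The double star appears for the glucocorticoid list after TAA at day 7 (0.53) and between DEX and TAA at day 7 (-0.46).

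The change of each drug effect between the days was tested directly. For TAA, the glucocorticoid list effect was lower at day 30 than at day 7 by a mean of -0.42 (95% interval -0.79 to -0.06), with Zbtb16 at -0.66 ± 0.22, Mt1 at -1.22 ± 0.40, Mt2 at -1.42 ± 0.53 and Fkbp5 at -0.80 ± 0.41. Fkbp5 was at -0.26 without TAA day 7 replicate 1. The call of the list was lost otherwise (adjusted p = 0.169 with an estimated correlation). The gliosis effect of TAA was lower by -0.91 (adjusted p = 0.588 with an estimated correlation), with Gfap at -1.86 ± 0.57, and without TAA day 7 replicate 2 it was -0.45 and did not pass. For DEX, the gliosis effect was lower at day 30 by a mean of -0.98, with Gfap (-2.10 ± 0.57) falling when adjusted over the list alone. The microglia effect was lower by -0.81, with Tmem119 (-0.74 ± 0.18) falling when adjusted over its list alone (adjusted p = 0.442 for both lists with an estimated correlation). The effect on the bipolar cell gene Scgn, which encodes a calcium sensor, fell by 0.79 ± 0.20 for DEX and fell by 0.99 ± 0.20 for TAA when adjusted over its list alone. Both values use the same 6 vehicle arrays, on which Scgn went from -0.08, -0.25 and -0.13 at day 7 to 0.49, 0.39 and 0.65 at day 30, so they are not independent. By limma, 0 genes passed for either drug, with 1558 for DEX and 1094 for TAA at an unadjusted p under 0.05, where chance gives 909.7; a fit on the compared arrays alone called 10 for DEX. With arrays weighted by their quality the counts were 1728 for DEX and 17 for TAA.

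The responses to the drugs were also compared across all 18193 genes, which are not independent replicates. At day 7 the DEX and TAA differences correlated at 0.379 (0.244 to 0.571 with 1 array left out), where 2 unchanged groups against the same vehicle arrays gave 0.499 in simulation; the covariance was lower than the simulated one by -0.0050. At day 30 the correlation was 0.210 (0.106 to 0.372 with 1 array left out, and 0.423 after quantile normalization) against a simulated 0.501, with a covariance difference of -0.0069. The simulation used independent genes and gave each gene the same spread on all arrays. The real spread over genes differed, with an SD of 0.163 to 0.179 on the BSS day 7 arrays and 0.378 on TAA day 7 replicate 2. The simulated values therefore cannot show whether the drug responses agree more or less than chance gives. With no arrays in common, DEX at day 30 and TAA at day 7 correlated at 0.216 (-0.193 to 0.359 with 1 array left out). DEX at day 7 and TAA at day 30 correlated at -0.257 (-0.353 to -0.135), the DEX effects of the 2 days at -0.0673 (-0.111 to -0.0302) and the TAA effects at -0.0462 (-0.203 to 0.143). Among these 6 pairs, 0 genes passed in both members of a pair. This carries no test, because every pair had at least 1 member with 0 genes called.

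Pooling the drugs or the days called 0 genes by limma in any of 5 contrasts. With arrays weighted by their quality the mean DEX effect called 789, the mean drug effect at day 30 called 127 and the mean TAA effect called 6. The counts at an unadjusted p under 0.05 were 557 for the mean drug effect at day 7, 1146 at day 30, 979 for DEX, 852 for TAA and 687 for all 4 effects. The glucocorticoid list averaged over both days of TAA was higher by 0.32 (95% interval 0.13 to 0.50; adjusted p = 0.0289 with an estimated correlation). Most of this mean comes from day 7 (0.53), and the day 30 value of 0.10 had an interval that includes 0 (-0.15 to 0.36). Of its 31 members, 5 rose when adjusted over the list alone, against 0 over all genes. Bipolar cell genes were higher over both drugs at day 7 by 0.17 (95% interval 0.06 to 0.28; adjusted p = 0.034 with an estimated correlation), and 1 of 15 members rose when adjusted over the list alone.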

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

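The tests of the change between days below were planned, and the tests that weigh explanations of the 3 patterns were chosen only after the results were seen.

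For DEX, the effect on 8 gene lists differed between day 30 and day 7 by the test of the difference itself with the preset correlation. None of the 8 did with an estimated correlation (adjusted p = 0.442 for each). The mean differences were -0.92 for interferon and antigen presentation, -0.81 for microglia and leukocytes, -0.98 for reactive gliosis and -0.59 for complement. They were -0.34 for extracellular matrix, -0.26 for bipolar cells, 0.44 for pigment epithelium and -0.21 for synapses. The synapse difference did not pass in 7 of the 12 fits that left out 1 array, for example -0.15 without DEX day 30 replicate 3. The bipolar and pigment epithelium differences did not pass in 2 such fits each. Sparc (-1.06 ± 0.24) and Mgp (-1.05 ± 0.31) passed when adjusted over the extracellular matrix list alone. Bsn (-0.72 ± 0.20), Rab3a (-0.73 ± 0.23) and Syn1 (-0.65 ± 0.21) did over the synapse list alone, and 0 genes passed over all genes.

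For TAA, 7 lists differed between the days with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.169. The mean differences were -0.91 for reactive gliosis, -0.42 for the glucocorticoid response, -0.52 for interferon and antigen presentation and 0.20 for cholesterol synthesis. They were -0.23 for bipolar cells, -0.31 for immediate early and heat shock genes and -0.25 for synapses. Without TAA day 7 replicate 2, the gliosis (-0.45), interferon (-0.05), bipolar (-0.16), immediate early (-0.21) and synapse (-0.22) differences did not pass.

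Outside the genes compared, 1 probe set unnamed here was lower in vehicle eyes at day 30 than at day 7 by limma over 45037 probe sets (-1.32, adjusted p = 0.0166).

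The first pattern is the higher level of glucocorticoid response genes after TAA at day 7. Leaving out any 1 of the 6 arrays gave a list mean of at least 0.44, which argues against 1 array carrying it. The 23 members found in no other list averaged 0.46 (95% interval 0.24 to 0.69), which argues against genes shared with other lists. The 19 Müller glia markers outside the list averaged 0.11 (-0.14 to 0.36), below the list mean. This cannot decide on more Müller glia RNA, because the interval overlaps that of the glucocorticoid list. The full Müller glia list also spread widely on the TAA arrays, from -0.19 to 0.39 (SD 0.30, against 0.05 in vehicle). An effect that had ended by day 30 and one that lasted cannot be told apart, because the change of -0.42 between the days passed only with the preset correlation (adjusted p = 0.169 with an estimated one). An action of the drug itself, which the design names, stays open as untested against other causes.

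The second pattern is that DEX day 30 replicate 3 was unlike replicates 1 and 2. A swap with a vehicle array of day 30 is argued against, since the highest correlation across genes of such an array with replicates 1 and 2 was 0.148, against 0.690 between these 2; swaps with arrays of other groups were not tested, and TAA day 7 replicate 2 had 0.339 and 0.415 with them. A wrong label on replicate 3 alone and a true difference between treated eyes cannot be told apart. That array had a mean correlation of 0.326 with the day 30 vehicle arrays, which had 0.203 among themselves, while its Gfap value of -0.93 lay below theirs (-0.19, -0.01 and 0.43) and on the side of replicates 1 and 2 (-1.32 and -1.59), for a gene that did not pass. A difference between animals was not tested, nor was whether replicates 1 and 2 are the unusual arrays.

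The third pattern is that crystallin genes differed between arrays. Their differences between groups passed only with the preset correlation, and arrays of 1 group also differed widely (SD 1.93 for TAA at day 30). Lens tissue carried over in the dissection may be the source, since the crystallin (14 genes) and other lens fibre lists (9 genes), which share no gene, correlated over the 18 arrays at Pearson r = 0.913 (permutation p = 1e-05) and Spearman correlation = 0.905 (permutation p = 1e-05, the smallest possible), the only relation computed in this family. Without the 2 arrays farthest out, TAA day 30 replicate 3 and BSS day 30 replicate 3, r was 0.892 (permutation p = 1e-05), and it was 0.886 within groups, 0.909 at day 7 and 0.939 at day 30. Retina is also known to express some crystallins, and a biological cause of the differences was not tested.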

How the results depend on the processing

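Leaving out the lower part of the genes by interquartile range, leaving out the 2 arrays of widest spread (replicate 2 of TAA at day 7 and at day 30) and keeping only list members found in no other list were chosen after seeing the data. The other fits were planned. The centred values allowed no filter on level, so a fit without a filter equals the one reported, and the stricter filter was not run. A correlation over called genes only was not run either, because 0 genes were called in both comparisons. No result that passed in either fit reversed its direction, and a 1.5-fold minimum changed no count. With 1 array left out, 2 of the correlations between comparisons and several means of the glucocorticoid list near 0 turned their sign, such as DEX at day 30 (0.01, and -0.08 without BSS day 30 replicate 2).

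With every probe set tested, DEX against TAA at day 7 called 0 genes. With the mean of a gene's probe sets, TAA called 3 genes at day 7 and 1 at day 30. Lists passing were then 14 for TAA at day 7 and 2 for DEX against TAA at day 30. With quantile normalization the counts were 2 for TAA at day 7, 2 for DEX against TAA at day 7, 50 for vehicle between days and 1 for the mean TAA effect. Lists passing were then 8 for TAA at day 7, 5 for TAA at day 30, 7 for DEX against TAA at day 7 and 0 at day 30. The correlation of the DEX and TAA differences at day 30 was then 0.423. With a common array median, DEX against TAA at day 7 called 0. With only the compared arrays, whose fits have fewer residual degrees of freedom by construction, the counts were 2 for DEX at day 7, 0 for TAA at day 7, 0 for DEX against TAA at day 7, 3 for vehicle between days and 10 for the change of the DEX effect. A variance trend with robust moderation called 0 for TAA at day 7 and 0 for DEX against TAA at day 7. At an adjusted p under 0.1 the counts were 2 for TAA at day 7, 1 for TAA at day 30, 323 for DEX against TAA at day 30 and 1 for the mean TAA effect.

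Array quality weights moved the most counts. They called 164 genes for DEX and 49 for TAA at day 7, and 2699 for DEX and 1 for TAA at day 30. DEX against TAA called 747 at day 7 and 2367 at day 30, and vehicle between days 527. The changes of the DEX and TAA effects called 1728 and 17, the mean drug effect at day 30 127, the mean DEX effect 789 and the mean TAA effect 6. The weights ran from 0.195 on TAA day 30 replicate 2 to 4.15 on TAA day 7 replicate 3. They were estimated from the same values that were tested, so they are no independent measure of array quality.

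With the replicate number as a block, the counts were 0 for TAA at day 7, 1 for TAA at day 30, 0 for DEX against TAA at day 7 and 101 at day 30. Deviations of same-numbered arrays correlated from -0.215 to 0.427. Vehicle between days called 7 with the block and the other counts of genes were the same. The synapse list no longer passed for the change of the DEX effect.

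With an estimated correlation, which widens the test by construction where it exceeds the preset one, the lists passing were 0 for DEX at day 7, 1 for TAA at day 7, 0 for DEX at day 30 and 0 for TAA at day 30. They were 1 for DEX against TAA at day 7 and 0 at day 30, 0 for vehicle between days, 0 for the change of the DEX effect and 0 for that of the TAA effect. Without the lower part by interquartile range the mean TAA effect called 1. Without the 2 widest arrays the counts were 27 for DEX at day 30, 152 for DEX against TAA at day 30, 11 for vehicle between days, 14 for the change of the DEX effect and 1 for the mean drug effect at day 30. Lists passing were then 8 for TAA at day 7, 4 for TAA at day 30, 12 for DEX against TAA at day 7 and 3 at day 30, and 4 for the change of the TAA effect. With members found in no other list, angiogenesis after DEX at day 7 (0.09) and complement after DEX at day 30 (-0.25) no longer passed.

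Leaving out 1 array at a time, which leaves 2 in a group, gave counts of 0 to 1 for DEX and 0 to 15 for TAA at day 7, and 0 to 695 for DEX and 0 for TAA at day 30. DEX against TAA ran from 0 to 5 at day 7 and 0 to 1253 at day 30, and vehicle between days from 0 to 5. The changes of the DEX and TAA effects ran from 0 to 1 and 0 to 2, the mean drug effect from 0 to 1 at day 7 and 0 to 2 at day 30, the mean DEX effect from 0 to 1 and the mean TAA effect from 0 to 4. All effects pooled stayed at 0. Lists passing ran from 10 to 14 for DEX and 5 to 13 for TAA at day 7, and 0 to 5 for each at day 30. They ran from 3 to 12 for DEX against TAA at day 7, 0 to 4 at day 30, 0 to 6 for vehicle between days, 5 to 10 for the change of the DEX effect and 2 to 12 for that of the TAA effect. Of the values of single genes, 3591 kept their side of the threshold in the planned fits with all arrays, 125 passed where they had not and 12 no longer passed. With 1 array left out these numbers were 3487, 30 and 29. Apart from the constructions named, the cause was not tested.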

Other observations

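The tests of this part were planned. Lists that passed in none of the 7 comparisons of 3 arrays against 3 are given here as ranges, and not passing does not show that they stayed unchanged. Rod photoreceptor genes had mean differences from -0.10 (TAA at day 30) to 0.09 (DEX against TAA at day 30), and cone genes from -0.13 (TAA at day 7) to 0.07 (DEX against TAA at day 30). The rod list was lower over both days of TAA by -0.09 (95% interval -0.18 to -0.01) with the preset correlation alone (adjusted p = 0.633 with an estimated correlation), and likewise over both drugs at day 7 by -0.06 (adjusted p = 0.477). These rod values rest largely on the 2 arrays of widest spread, at -0.21 (TAA day 7 replicate 2) and -0.17 (TAA day 30 replicate 2), while the other TAA arrays were at 0.02 and -0.06 at day 7 and at -0.01 and -0.01 at day 30. Vascular endothelium and barrier genes, which include those of the inner blood-retinal barrier, ran from -0.09 to 0.08, pericyte and smooth muscle genes from -0.08 to 0.09, and water and ion transport genes from -0.03 to 0.12. Inflammatory mediators ran from -0.08 to 0.11, cell death and growth arrest genes from -0.10 to 0.16 (the highest after TAA at day 7, 95% interval 0.06 to 0.26), and circadian clock genes from -0.03 to 0.11. Over both drugs at day 7 the cell death list passed with the preset correlation alone (0.11, adjusted p = 0.0967 with an estimated one). Cell cycle genes ran from -0.07 to 0.07, oxidative phosphorylation genes from -0.11 to -0.01, anterior segment genes from -0.10 to 0.14 and erythrocyte genes from -0.18 to 0.06. Cholesterol synthesis genes were at -0.09 after TAA at day 7 and 0.11 at day 30, and the change of 0.20 between the days had the leading members Mvd (0.57 ± 0.21), Fdps (0.43 ± 0.16) and Sc5d (0.45 ± 0.17), none of which passed.

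Other splits of the same arrays were counted for every result across genes, as planned. For the 7 comparisons of 3 arrays against 3, the 10 splits are too few to reach a share under 0.05. Counts of genes in the real split and in the highest other split were 0 and 1 for DEX at day 7, 1 and 0 for TAA at day 7, 0 and 5 for DEX at day 30 and 0 and 0 for TAA at day 30. They were 1 and 0 for DEX against TAA at day 7, 0 and 210 at day 30, and 5 and 0 for vehicle between days. Counts of lists passing were 12 and 6 for DEX at day 7, 4 and 10 for TAA at day 7, 4 and 10 for DEX at day 30 and 2 and 8 for TAA at day 30. They were 4 and 14 for DEX against TAA at day 7, 1 and 9 at day 30, and 3 and 9 for vehicle between days. For the changes between days, 9 of 100 splits gave at least the 8 lists of DEX (highest other 13) and 54 of 100 at least the 7 of TAA (highest other 13), so chance is not excluded for either. A count of 0 genes is met by every split by construction (100 of 100 or 84 of 84 for the changes between days and the pooled effects), so these splits carry no test of it. The highest other counts there were 1 for the change of the DEX effect, 94 for that of the TAA effect, 86 and 491 for the mean drug effect at day 7 and day 30, 1 for the mean DEX effect, 12 for the mean TAA effect and 556 for all effects. The splits with 86, 94, 210, 491 and 556 genes against a real count of 0 point to a structure of the arrays other than the groups, whose nature was not tested.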
